A study of Mus musculus with 6 samples.

How the data were processed

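Gene expression was measured by RNA sequencing in 6 libraries of mouse fully-grown germinal vesicle oocytes, 3 control and 3 Uba3 conditional knockout (Uba3 cKO), each from a pool of about 150 oocytes. Per the labels' protocols, RNA was extracted with the PicoPure kit and libraries were made with an Illumina TruSeq RNA kit and sequenced on a NovaSeq. Whether the kit selected polyadenylated RNA or removed ribosomal RNA was not given in the sources used here. Group and replicate number were taken from each sample's title.

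The submitters' processing notes name fastp, STAR, featureCounts, DESeq2 and the genome build GRCm39, without versions, order or settings. The strand setting of the counting and the treatment of reads that map to several places were not given in the sources used here, so genes with near-identical copies, overlapping genes and antisense genes are uncertain. The deposited table holds log2 values, normalized between libraries by the authors, for 28738 Ensembl gene IDs. The unit was read from the values, which ran from 0.0363 to 18.01 with no exact 0. The spread between replicates shrank at low levels, which is the shape of a regularized logarithm, but the table does not name its transform. If it is one, fold changes of genes at low levels are shrunken and understate the change, which was not tested. No read counts or library totals were used, so the depth of each library is unknown and no counting interval is given. The highest sum of linear values of a library was 1.05 times the lowest, which reflects the authors' scaling and is not a depth.

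Symbols, chromosome, gene order, biotype, transcript length and GC content were taken from GENCODE M21, an annotation of an earlier mouse build than the one the submitters named, so no coordinates are given. A symbol was found for 27660 IDs (96.2%), and 1078 IDs had none. All columns of values were used.

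Genes were kept when their linear value (2 to the power of the deposited value) was 10 or more in at least 3 of the 6 libraries, which kept 17450 genes and dropped 11288. Uba3 cKO and control libraries were compared with limma 3.58.1 in R 4.3.3, with an intensity trend, on the deposited log2 values. The design written before the data were examined had assumed linear normalized values and log2(value + 1). Because the table was already on a log2 scale, no pseudocount was added in the reported fit. Pseudocounts of 0.5, 1 and 5 on the linear scale were tried as alternatives. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Every adjusted p of a gene in the text comes from this limma fit unless another test is named. Differences are Uba3 cKO minus control on the log2 scale. The labels do not say that the pools came from separate animals, so p-values measure only the spread between these pools.

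Before the data were examined, 36 gene lists were fixed, 4 of them markers of other ovarian cell types. Of their 1245 entries, 26 were not matched. Each list was tested with limma's camera at a preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the 36 lists. Camera with an estimated correlation and fry were run beside it. Camera compares a list with the other genes, while fry asks whether the genes of a list move, on balance, one way. For single values of 3 against 3 libraries, an exact two-sided permutation test was used, and the smallest p it can give is 0.1.

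The genes named were chosen by a rule fixed in advance. It took Uba3 and the mitochondrial DNA-encoded mRNAs. It took the 8 genes with the largest change in each direction among called genes with a mean linear value of 50 or more in the higher group and no overlap between the groups, leaving out predicted models, clones and pseudogenes. From each list it took up to 4 called members with the smallest adjusted p, or, where none was called, up to 2 members with the highest level. Some genes that the rule takes are not reported here. Genes named outside this rule are marked as chosen after their values were seen.

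The fit was tested on data simulated for Uba3 cKO against control over 17450 genes. It recovered 24% of the genes changed by 0.3 on the log2 scale, 88% at 0.6, 98% at 1 and 100% at 1.5. Of its 160 calls, 4 (2.5%) were false. Simulated genes varied independently of each other, and far fewer were changed than the 1421 called in the real data. The rates of recovery and of false calls may thus differ in the real data. Alternatives covered the pseudocount, the filter, the scaling between libraries, the variance model, sample weights, a replicate block, the threshold, the list test and leaving out each library. A correction of each library for transcript length and GC content, that correction with the replicate block, and the pseudocount of 1 were chosen after seeing the data.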

Results

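Fully-grown oocytes at the germinal vesicle stage, which are arrested in prophase of the first meiotic division, were compared between control mice and mice with a conditional knockout of Uba3. Uba3 encodes the catalytic subunit of the enzyme that activates NEDD8, a ubiquitin-like protein. The best-known targets of NEDD8 are the cullins, the scaffolds of cullin-RING ubiquitin ligases. The series title places the study in the context of mitochondrial transcription and oocyte quality, so the transcripts of mitochondrial DNA formed a comparison of their own. Each group had 3 libraries, each from a pool of about 150 oocytes. Values are the authors' normalized log2 values, and the depth of each library is unknown. Across the 17450 kept genes, Pearson correlations lay between 0.997 and 0.998 within each group and between 0.995 and 0.997 across the groups. The first principal component held 49.1% of the variance and separated the groups.

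The targeted gene was lower in every Uba3 cKO library than in every control library. Uba3 (ENSMUSG00000030061, chromosome 6) fell from 11.39 ± 0.06 (SD, n = 3) in control oocytes to 10.18 ± 0.16 (SD, n = 3) in Uba3 cKO oocytes. The difference was -1.21 on the log2 scale (SE 0.10), a 2.31-fold lower level, with an adjusted p of 2.07e-05 in limma. An exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 libraries allow. Which part of the gene was deleted was not given in the sources used here, and the remaining level can include transcript outside it.

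Most other genes of the NEDD8 pathway were not called. Of the 26 kept members of that list, Uba3 fell, Cops7b rose and 24 were not called, and adjusted over the list alone the counts were the same. Cops7b, a subunit of the COP9 signalosome that removes NEDD8 from cullins, rose by 0.42. Its call ended without any single library other than Uba3 cKO replicate 2 (adjusted p up to 0.13). Among the 39 kept subunits of cullin-RING ligases, 2 rose, also adjusted over the list alone, and none fell. Cul5, a cullin scaffold, rose by 0.77 (SE 0.09, adjusted p = 1.46e-04). Klhl22, a substrate adaptor for CUL3, rose by 0.63 (SE 0.10, adjusted p = 0.00229). Among 28 kept genes for cullin-RING ligase substrates and replication licensing, Ccne2, a cyclin E, rose by 0.50 and Wee1, an inhibitory kinase of CDK1, rose by 0.48. No other member was called, and the count was the same adjusted over the list alone. The call of Wee1 ended without control replicate 3 or Uba3 cKO replicate 1 (adjusted p up to 0.0518). None of these 3 lists was called by camera, with adjusted p of 0.255, 0.618 and 0.691.

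More genes were higher than lower in Uba3 cKO oocytes. Under the naming rule, the largest rise was in Frmd3, which encodes a FERM domain protein, with a log2 difference of 1.82 (SE 0.13). Tceal8, a member of an X-linked family of transcription elongation factor-like genes, rose by 1.66 (SE 0.12). Trim6, a tripartite motif ubiquitin ligase, rose by 1.65 (SE 0.10), a 3.13-fold change. Mfhas1 rose by 1.55, Drc1, a component of the dynein regulatory complex of motile cilia, by 1.55, Cltrn, which encodes collectrin, by 1.51, the homeobox gene Hdx by 1.51, and Arhgap24 was 2.84-fold higher. All 8 had adjusted p of 2.08e-05 or less. Tceal8 and Trim6 belong to families with similar members, whose reads the counting could have divided differently.

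**Figure D1:**
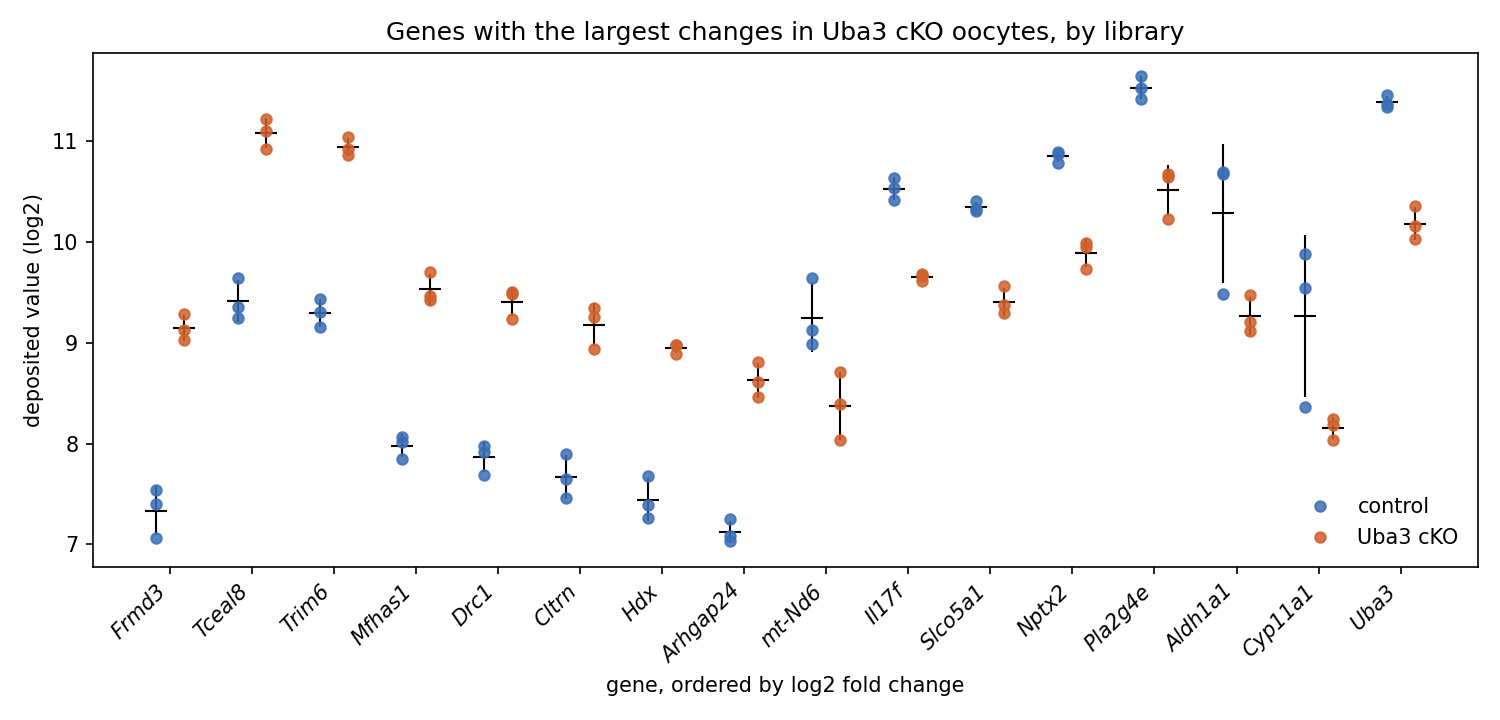
Deposited log2 values (vertical axis) of the 16 genes with the largest changes under the naming rule (horizontal axis), in control and Uba3 cKO libraries. Points are libraries, horizontal bars are means and vertical bars are SD (n = 3). The groups do not overlap for any of the 16 genes, and Cyp11a1 and Aldh1a1 vary widely among the control libraries.

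Among genes taken by the naming rule, the largest falls were smaller than the largest rises. After Uba3, the largest of these falls was in Cyp11a1, the cholesterol side-chain cleavage enzyme that begins steroid synthesis (-1.11, SE 0.27, adjusted p = 0.0210). Aldh1a1, a retinaldehyde dehydrogenase, came next (-1.02, SE 0.24, adjusted p = 0.0183). Pla2g4e, a cytosolic phospholipase, fell by 1.02 (SE 0.12), Nptx2, a neuronal pentraxin, by 0.96 (SE 0.10), Slco5a1, a solute carrier, by 0.94 (SE 0.10), and the cytokine gene Il17f by 0.88 (SE 0.10). mt-Nd6, a mitochondrial gene for a complex I subunit, fell by 0.88 (SE 0.18). Cyp11a1 stood at 8.36, 9.88 and 9.55 in control replicates 1, 2 and 3 and between 8.04 and 8.25 in the Uba3 cKO libraries. It is a member of the list of theca, stroma and luteal markers, which had a median of -0.29 and mean deviations from the average library of -0.05, 0.28 and 0.32 in the same controls, and Aldh1a1 is a member of the list of granulosa and cumulus markers, with a median of -0.09. The call of Cyp11a1 ended without control replicate 2, control replicate 3 or Uba3 cKO replicate 3 (adjusted p up to 0.103). The call of Aldh1a1 ended without control replicate 2, control replicate 3 or Uba3 cKO replicate 1 (adjusted p up to 0.0990).

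In all, 1421 of the 17450 genes were called, 984 higher and 437 lower in Uba3 cKO oocytes. Most changes were modest. The median log2 difference was 0.46 among higher genes and -0.42 among lower genes, and 38 higher and 5 lower genes changed by 1 or more. The groups did not overlap for 978 of the higher and 432 of the lower genes. Over all tested genes they did not overlap for 4873, where chance gives 10%. Leaving out 1 library gave 780 calls without control replicate 2, 618 without control replicate 3, 681 without Uba3 cKO replicate 1 and 709 without Uba3 cKO replicate 3.

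The 11 kept mRNAs encoded by mitochondrial DNA had a median log2 difference of -0.26. As a list they were called lower by camera (adjusted p = 3.67e-04). With an estimated correlation of 0.32 against the preset 0.01, camera gave an adjusted p = 0.84, and fry gave 0.278. Of these mRNAs, mt-Nd6 (-0.88, adjusted p = 0.00786) and mt-Cytb, the cytochrome b gene of complex III (-0.38, adjusted p = 0.0281), fell and 9 were not called. Adjusted over the list alone, 6 fell. The other log2 differences were -0.38 for mt-Nd5, -0.38 for mt-Nd4, -0.27 for mt-Co1, -0.26 for mt-Nd3, -0.23 for mt-Nd2, -0.21 for mt-Nd1, -0.11 for mt-Co3, and -0.02 for both mt-Co2 and mt-Nd4l. The mitochondrial share of the summed linear values was 0.238% ± 0.018 (SD, n = 3) in control and 0.196% ± 0.028 (SD, n = 3) in Uba3 cKO libraries (exact two-sided permutation p = 0.2). This share weights RNAs by level, so mt-Co1, the most abundant, weighs most in it. In every library the median log2 value of the kept mRNAs was that of mt-Nd4. It was 10.45 ± 0.26 (SD, n = 3) in control and 10.08 ± 0.21 (SD, n = 3) in Uba3 cKO libraries (exact two-sided permutation p = 0.3). That test thus reflects mt-Nd4 alone. Chosen after their values were seen, the ribosomal RNAs mt-Rnr1 (-0.49) and mt-Rnr2 (-0.71) and the transfer RNA mt-Tq (-0.69) were also called lower. All 22 kept mitochondrial RNAs had a log2 difference below 0. The levels of mt-Co2 (3.42), mt-Nd4l (3.82), mt-Co3 (5.85) and mt-Nd3 (6.28) in control oocytes were far below that of mt-Co1 (15.36), and mt-Atp8 was not analysed here. The level filter dropped mt-Atp6 (2.36 in control). Nuclear copies could have taken reads of mt-Co2, mt-Nd4l, mt-Co3 and mt-Nd3, so their differences are uncertain. The list median of -0.26 is the value of mt-Nd3. The call of mt-Cytb ended without control replicate 1, control replicate 3, Uba3 cKO replicate 1 or Uba3 cKO replicate 3 (adjusted p up to 0.143).

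**Figure D2:**
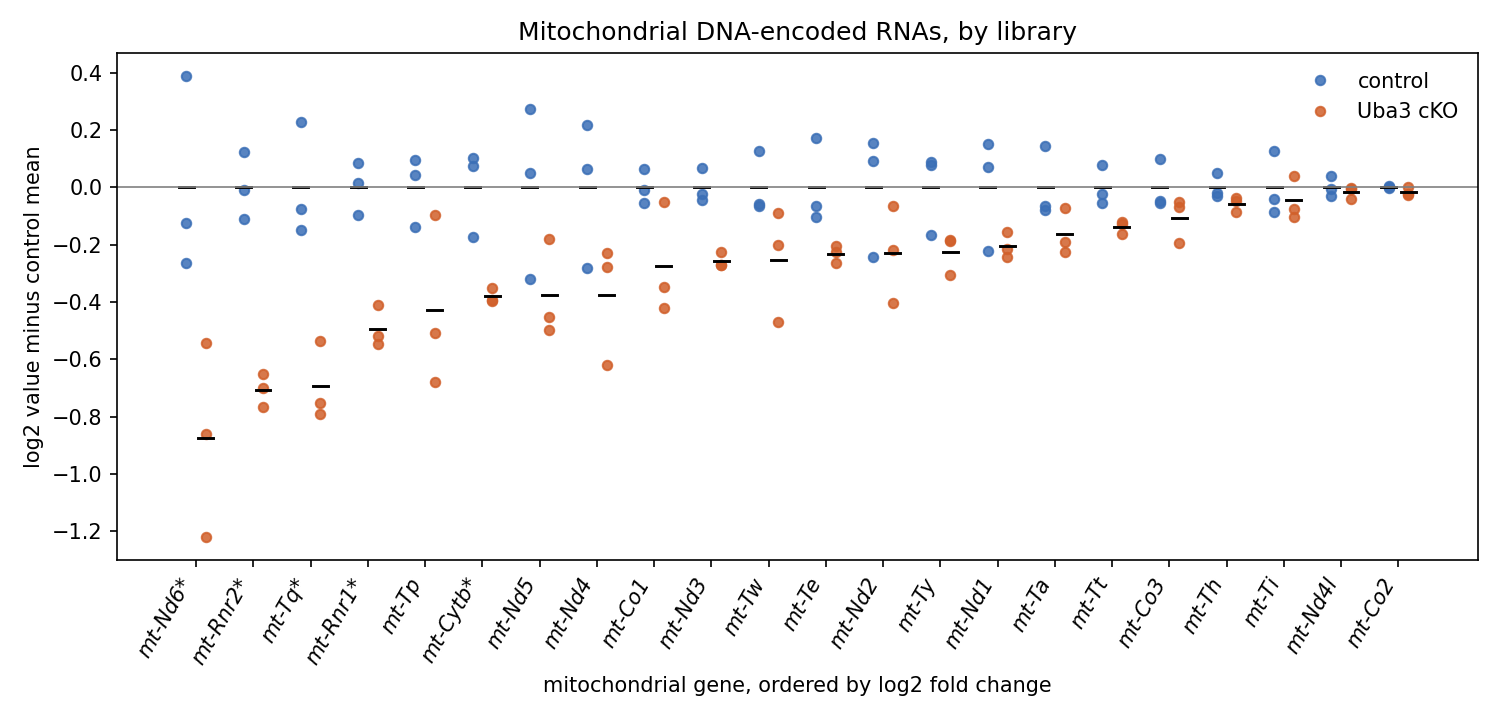
Log2 value of each library minus the control mean (vertical axis) for the 22 kept mitochondrial RNAs (horizontal axis). Points are libraries, bars are group means (n = 3) and asterisks mark the 5 genes called lower, from mt-Nd6 at -0.88 to mt-Cytb at -0.38; the mean of Uba3 cKO libraries lies below 0 for all 22.

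Single nuclear genes for mitochondrial transcription were called, in both directions. Of 42 kept genes for mitochondrial transcription and DNA maintenance, 2 rose and 3 fell, and adjusted over the list alone 3 rose and 3 fell. Polrmt, the mitochondrial RNA polymerase, fell by 0.44, and Twnk, the mitochondrial DNA helicase, by 0.43. Supv3l1, an RNA helicase chosen after its value was seen, fell by 0.31. Trmt10c, a subunit of mitochondrial RNase P, rose by 0.39, and Ppargc1a, a transcriptional coactivator near the low end of the range at 4.19 in control, rose by 0.17. This list was not called by camera (adjusted p = 0.413). The calls of these genes ended without control replicate 3 or Uba3 cKO replicate 3, and also without control replicate 2 or Uba3 cKO replicate 2 for Polrmt, control replicate 1 or Uba3 cKO replicate 1 for Twnk, control replicate 2 or Uba3 cKO replicate 1 for Trmt10c and any of the 6 libraries for Ppargc1a (adjusted p up to 0.189, 0.167, 0.215 and 0.125). After the length and GC correction the difference of Ppargc1a was 0.10 (adjusted p = 0.345). Supv3l1 was not refitted by library.

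Lists of structural genes of the respiratory chain and ribosomes had small negative medians. The median log2 difference was -0.12 for 37 nuclear complex I subunits and -0.12 for 41 subunits of complexes II to V, and no member of either was called, over all genes or adjusted over the list alone. It was -0.14 for 77 mitochondrial ribosomal proteins, of which 5 fell and 1 rose by either adjustment. Mrpl9 fell most, by 0.74 (adjusted p = 4.76e-04). It was -0.15 for 77 cytosolic ribosomal proteins, of which 2 fell, including Rpsa (-0.35), and 75 were not called, and none was called adjusted over the list alone. Camera called these 4 lists lower, with adjusted p of 0.0343, 0.00381, 4.49e-05 and 3.47e-05, and each had an adjusted p = 0.84 with an estimated correlation. The estimated correlations were 0.28, 0.32, 0.20 and 0.40, far above the preset 0.01. If they hold, the p-values at the preset correlation are too small. The call of the complex I list ended without control replicate 2, control replicate 3 or Uba3 cKO replicate 3 (adjusted p up to 0.339), and that of the complex II to V list without control replicate 2 (adjusted p = 0.339, median -0.03). Without control replicate 2 the medians were also smaller for complex I (-0.06), mitochondrial ribosomal proteins (-0.08) and cytosolic ribosomal proteins (-0.10), and without control replicate 1 that of complexes II to V was -0.19. The call of Rpsa ended without control replicate 2, control replicate 3, Uba3 cKO replicate 1 or Uba3 cKO replicate 3 (adjusted p up to 0.161).

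**Figure D3:**
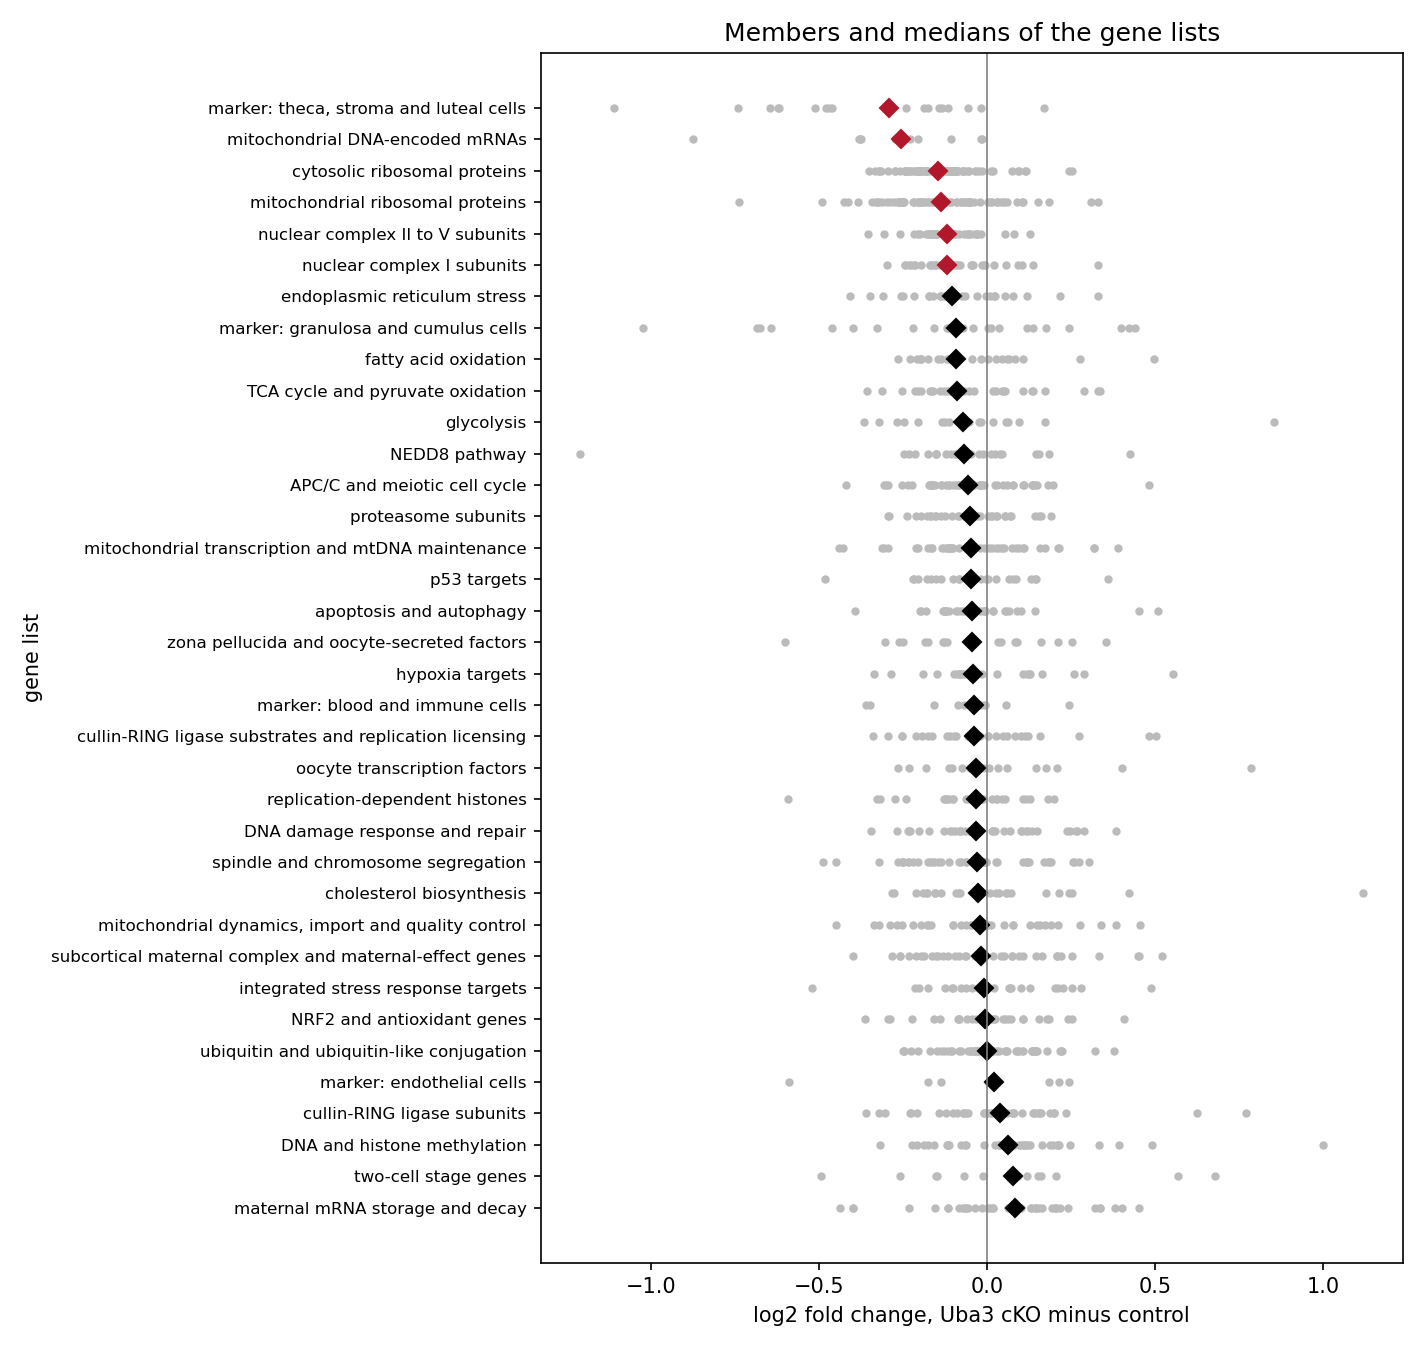
Log2 fold change of Uba3 cKO against control (horizontal axis) for the 36 gene lists (vertical axis). Grey points are kept members and diamonds are list medians, red where camera with the preset correlation called the list. The 6 red lists have medians from -0.29 to -0.12, and none of them was called with an estimated correlation.

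The list of theca, stroma and luteal markers had a median log2 difference of -0.29. Of its 19 kept members 6 fell, including Col3a1 (-0.62), Dcn (-0.51) and Acta2 (-0.74), and 13 fell adjusted over the list alone. Camera called it lower (adjusted p = 1.14e-06). With an estimated correlation of 0.45 against the preset 0.01, camera gave an adjusted p = 0.84, and fry gave 0.306. The list's median was -0.48 under the stricter filter. Its mean deviation from the average library was -0.05, 0.28 and 0.32 in control replicates 1, 2 and 3 and -0.17, -0.11 and -0.27 in the Uba3 cKO replicates. Whether the pools differed in their amount of such cells was not tested, so lower markers cannot be assigned to the oocytes. Control replicate 2 also had the highest mean deviation of the nuclear complex I list (0.14), the complex II to V list (0.18), the mitochondrial ribosomal list (0.15) and the cytosolic ribosomal list (0.18). For the mitochondrial mRNAs it had -0.01, against 0.20 and 0.23 in control replicates 1 and 3. Among 25 kept granulosa and cumulus markers, Kitl (0.44) and Fshr (0.42) rose and Aldh1a1 (-1.02) and Inhba (-0.69) fell, while adjusted over the list alone 2 rose and 5 fell. Of 13 kept blood and immune markers Hbb-bs (-0.36) and C1qb (-0.35) fell, and of 11 endothelial markers Tie1 (-0.59) fell, with the same counts adjusted over each list alone. Camera called none of these 3 lists, with adjusted p of 0.274, 0.255 and 0.852. The call of Acta2 ended without control replicate 2, control replicate 3 or Uba3 cKO replicate 3, and that of Inhba without control replicate 2 or Uba3 cKO replicate 3 (adjusted p up to 0.0708 and 0.0890). That of Kitl ended without control replicates 2 or 3 or Uba3 cKO replicates 1 or 3, that of Fshr without control replicates 1 or 2 or Uba3 cKO replicates 1 or 2, that of Hbb-bs without control replicates 1 or 3 or Uba3 cKO replicates 1 or 3, and that of C1qb without any of the 6 libraries (adjusted p up to 0.111, 0.108, 0.0954 and 0.198). Camera called the granulosa and cumulus list lower without Uba3 cKO replicate 2 (adjusted p = 0.00746) and the blood and immune list lower without control replicate 2 (adjusted p = 0.0330).

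Single members of 5 lists of oocyte genes were called. Of 19 kept zona pellucida and oocyte-secreted factors 3 fell and none rose. Zp2, a zona pellucida glycoprotein, fell by 0.30 from 16.32, and the growth factor genes Bmp15 and Fgf8 fell by 0.25 and 0.60. Of 21 oocyte transcription factors and regulators, Obox7 rose by 0.78 (adjusted p = 7.95e-05) and Dazl, an RNA-binding protein, by 0.40. Obox7 belongs to a cluster of similar homeobox genes, so its reads are uncertain. Of 38 maternal-effect genes, Sall4, a zinc-finger transcription factor, rose by 0.52 and Zfp36l2, which promotes mRNA decay, by 0.45. Of 15 kept 2-cell stage genes, Dppa4 (0.68) and B020004J07Rik (0.57) rose and Sp110 (-0.49) fell. These 4 counts were the same adjusted over each list alone. Of 42 genes of maternal mRNA storage and decay 3 rose, including Dcp2, a decapping enzyme (0.32), and 2 fell, Pabpn1l (-0.44) and Tent2 (-0.40), and adjusted over the list alone 6 rose and 3 fell. Camera called none of these 5 lists (adjusted p of 0.365, 0.920, 0.618, 0.358 and 0.255). Under quantile normalization Zp2 was not called (-0.14, adjusted p = 0.0537), and the difference of Bmp15 was 0. That method gives 0 to any gene with the same rank in every library, so this value says nothing about Bmp15. The call of Zp2 also ended without control replicate 3 (adjusted p = 0.0543). That of Bmp15 ended without any library but control replicate 3 (adjusted p up to 0.134). Those of Fgf8 and Pabpn1l ended without control replicates 2 or 3 or Uba3 cKO replicates 2 or 3 (adjusted p up to 0.182 and 0.111). That of Dazl ended without control replicates 2 or 3 or Uba3 cKO replicates 1 or 3, and that of Zfp36l2 without control replicates 2 or 3 or Uba3 cKO replicates 1 or 2 (adjusted p up to 0.211 and 0.115). That of Dcp2 ended without control replicate 3 or Uba3 cKO replicates 1 or 3, and that of Tent2 without Uba3 cKO replicates 1 or 3 (adjusted p up to 0.13 and 0.0614).

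Among genes of chromatin and cell division, Tet1 and Tet2, which oxidize 5-methylcytosine, rose from 8.52 to 9.52 (SE of the difference 0.13) and by 0.49 (SE 0.09), and the histone methyltransferase gene Ehmt1 fell by 0.32. They were 3 of 40 kept genes of DNA and histone methylation. Of 49 genes of the anaphase-promoting complex and meiotic cell cycle, Wee1 rose by 0.48 and Cdc25c, a phosphatase that activates CDK1, fell by 0.42. Of 45 genes of the spindle and chromosome segregation 4 fell, Tuba1c (-0.49), Spire2 (-0.45), Spire1 (-0.32) and, chosen after its value was seen, Prc1 (-0.25), and the cohesin acetyltransferase gene Esco2 rose by 0.30. Of 29 genes in the list of replication-dependent histones, only H1f0 (-0.59) was called, and that linker histone is not replication-dependent. None of 36 genes of DNA damage response and repair was called, with 0.27 for Trp53bp1 and -0.11 for Brca2. Counts were the same adjusted over each list alone, and camera called none of the 5 lists (adjusted p of 0.431, 0.255, 0.274, 0.365 and 0.920). The call of Ehmt1 ended without any of the 6 libraries, that of Spire1 without any but control replicate 1, and that of Esco2 without any but Uba3 cKO replicate 2 (adjusted p up to 0.142, 0.123 and 0.217). That of Cdc25c ended without control replicates 2 or 3 or Uba3 cKO replicate 1, that of Spire2 without control replicates 2 or 3 or Uba3 cKO replicates 2 or 3, that of Tuba1c without Uba3 cKO replicate 3 and that of Wee1 without control replicate 3 or Uba3 cKO replicate 1 (adjusted p up to 0.0897, 0.156, 0.0506 and 0.0518). Camera called the histone list lower without control replicate 3 (adjusted p = 6.42e-05).

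Metabolic and stress genes showed single changes within lists that camera did not call. Stard4, a sterol transfer protein, rose by 1.12 (SE 0.11, adjusted p = 5.62e-05), and 2 of 26 cholesterol genes rose in all. Slc16a1, a monocarboxylate transporter, rose by 0.85 and Gpi1 fell by 0.32 among 19 glycolysis genes, where adjusted over the list alone 1 rose and 4 fell. Pfkfb3, a regulator of glycolysis, rose by 0.55 among 22 hypoxia targets, and Acsl4 by 0.50 among 24 genes of fatty acid oxidation. Of 31 genes of the TCA cycle and pyruvate oxidation, Idh3g rose by 0.34 and the mitochondrial pyruvate carrier gene Mpc1 fell by 0.36, and none was called adjusted over the list alone. Of 39 genes of mitochondrial dynamics, import and quality control, the mitophagy receptor gene Fundc1 (0.46) and the fusion gene Mfn1 (0.34) rose and Timm50 (-0.45) fell, and adjusted over the list alone 3 rose and 2 fell. Of 27 genes of endoplasmic reticulum stress, the chaperone gene Hspa5 (-0.41), Manf (-0.35) and Atf6 (-0.31) fell, and adjusted over the list alone 1 rose and 3 fell. Xiap, an inhibitor of caspases, rose by 0.51 and Casp8, an initiator caspase, by 0.45 among 36 genes of apoptosis and autophagy. Cth (0.49) was the 1 call among 26 targets of the integrated stress response, Gsta4 (0.41) the 1 among 32 NRF2 and antioxidant genes, and Trp63 (0.36) and Btg2 (-0.48) the 2 among 26 p53 targets. None of 38 proteasome subunits or 51 genes of ubiquitin conjugation was called. Counts of the other lists were the same adjusted over each list alone. Camera's adjusted p for these 13 lists lay between 0.101 and 0.920, and the list of endoplasmic reticulum stress was called lower without control replicate 2 (adjusted p = 0.0147). Median, mean and test differed in sign for the lists of cholesterol synthesis, hypoxia targets, integrated stress response, maternal-effect genes, NRF2 and antioxidant genes, ubiquitin conjugation, endothelial markers, and oocyte transcription factors. Calls in this paragraph that held without each library in turn were those of Stard4, Slc16a1, Pfkfb3 and Xiap. That of Casp8 ended without control replicate 3 (adjusted p = 0.0527). Those of Idh3g and Mpc1 ended without any of the 6 libraries, and those of Gpi1, Mfn1, Manf and Atf6 without any but control replicate 1 (adjusted p up to 0.181, 0.135, 0.131, 0.162, 0.157 and 0.151). That of Acsl4 ended without control replicates 2 or 3, and that of Btg2 without control replicate 3 or Uba3 cKO replicate 1 (adjusted p up to 0.0797 and 0.0712). That of Timm50 ended without control replicates 2 or 3 or Uba3 cKO replicate 3, and that of Hspa5 without control replicate 1 or Uba3 cKO replicates 1 or 3 (adjusted p up to 0.107 and 0.135). That of Fundc1 ended without control replicates 2 or 3 or Uba3 cKO replicates 2 or 3, that of Trp63 without control replicates 2 or 3 or Uba3 cKO replicates 1 or 3, that of Cth without control replicates 1 or 3 or Uba3 cKO replicates 2 or 3, and that of Gsta4 without control replicate 3 or any Uba3 cKO library (adjusted p up to 0.150, 0.157, 0.122 and 0.0933).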

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

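The pseudocount of 1 and the correction for transcript length and GC content were chosen after seeing the data. The naming rule took 83 called genes, and these kept their direction in each alternative that tested them, except Bmp15 under quantile normalization. Its difference was 0 there, which that method gives any gene with the same rank in every library. Of them, 50 stayed past the threshold in every such alternative that used all libraries and 33 in every fit that left out 1 library. With all libraries, calls ended without the trend for 20 of the 83, with the replicate block for 16 and with no filter for 13. Those that ended only without the trend were Acta2, Cth, Dazl, Hbb-bs, Hspa5, Inhba, Pabpn1l and Rpsa, only without the trend or in the robust fit Aldh1a1 and Cyp11a1, only with the replicate block Spire1, and only under quantile normalization Zp2. Others that ended under at least 1 such alternative included Atf6, Bmp15, C1qb, Cops7b, Dcp2, Ehmt1, Esco2, Fgf8, Gpi1, Idh3g, Manf, Mfn1, Mpc1, Mrps9, Polrmt, Ppargc1a, Spire2, Trmt10c, Trp63 and Twnk, and the cause was not tested. Genes named outside the rule were not followed in this way. The number of calls depended on which libraries were used. Leaving out 1 library gave 618 to 1637 calls, 482 to 1014 of them higher and 136 to 623 lower, and the cause was not tested. Fewer samples remain in such a fit, yet 1637 came without control replicate 1. Sample quality weights gave 2298 calls, 829 of them lower, and the cause was not tested. By construction, a stricter adjusted p of 0.01 left 518 calls, 417 higher and 101 lower, and a minimum log2 difference of 1 left 43, 38 higher and 5 lower. Of the 6 lists called by camera, 4 were called in every fit that left out 1 library. With an estimated correlation 0 lists were called, and by fry 0. The mitochondrial mRNAs, with a median of -0.26, then had an adjusted p of 0.84 and 0.278; over the other alternatives their adjusted p lay between 4.74e-06 and 0.00680.

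The values did not point to pairing by replicate number. Deviations of samples with the same number had correlations of -0.09, -0.20 and -0.05 across genes, and no sample correlated best with its own number. The positive correlations were control replicate 1 with Uba3 cKO replicate 2 (0.28), 2 with 3 (0.25) and 3 with 1 (0.19). Deviations sum to 0 within each group, so such correlations cannot settle whether samples were paired. The replicate block gave 1258 calls, and the complex I list was no longer called under it (adjusted p = 0.0508) or after the length and GC correction (adjusted p = 0.0930, or 0.116 with the replicate block). The count models planned as alternatives were not run, since whole reads could not be recovered from these log2 values. Depth is unknown, so what it limits could not be measured. In the simulated data, 24% of changes of 0.3 were recovered, but simulated genes were independent, so that share may not hold here.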

Other observations

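The tests of other splits of the libraries, of the scaling of mitochondrial RNA and of mitochondrial strand, the marker levels set against the rise, and the length and GC correction, were chosen after the result was seen; the test over gene name stems was added after the data were examined. An explanation was argued against where the value met the bound set for its absence and the whole interval excluded the value the explanation needs. The rule was changed 3 times after the values were seen: rules that differed between tests gave way to one close to the present rule, then to a stricter one asking that the whole interval clear the bound for absence, and then to the present one. The stricter rule would leave 3 explanations open: follicle cells, scaling of mitochondrial RNA, and strain variants near Uba3. Intervals over genes treat genes as independent, which they are not.

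X-linked genes were frequent among the genes that rose. Of 611 kept X-linked genes 68 rose and 8 fell. Besides Tceal8, Hdx and Cltrn they included Eda (1.06), a ligand of the tumor necrosis factor family, Cnga2 (1.02), a cyclic nucleotide-gated channel, Amot (0.73), and the cohesin subunit gene Stag2 (0.63), all chosen after their values were seen. Of 14 kept axonemal dynein heavy chain genes (Dnah) 6 rose and none fell. Those that rose included Dnah12 (from 9.45 to 10.44), Dnah6 (0.78) and Dnah14 (0.77), chosen after their values were seen. Enrichment of Dnah genes among those that rose had an adjusted Fisher's exact p of 0.0122 over 190 name stems. This enrichment was lost under many alternatives. After the length and GC correction 3 of them rose (adjusted p = 0.573), as with no filter (0.472) and without control replicate 2 (0.718), control replicate 3 (0.490), Uba3 cKO replicate 1 (0.673) or Uba3 cKO replicate 3 (0.414). It was also lost without Uba3 cKO replicate 2 (0.265), with the replicate block (0.502), under 3 of the 4 rescalings (0.465 to 0.527), with a pseudocount of 5 (0.13) and without the trend (0.0705).

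The 3 against 3 libraries allow 10 splits, too few for a share under 0.05. The real split gave 1421 calls and the highest other split 2, so 1 of 10 gave as many as the real one.

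More called genes were higher than lower (69.2%). Over 4 rescalings the lowest share was 63.6% (95% exact binomial interval 61.0 to 66.2), and after the length and GC correction it was 62.6% (60.03 to 65.1), where either cause needs 55% or less. The value after the correction argues against length and GC bias as the whole cause, although the correction took part of the excess away. The rescalings show only that the excess did not depend on the choice among them, and scaling beyond that stays open. Follicle cells left on the oocytes are argued against as the whole cause too: 8% of the 25 kept granulosa and cumulus markers rose (0.984 to 26.03) where over 50% were needed, and the difference between groups in their library medians was -0.03 (2 SE over libraries, -0.25 to 0.20), or 0.06 (-0.10 to 0.22) for the 8 at or below the median level of the higher genes, against a median rise of 0.46; the median log2 difference was -0.09 for these markers and -0.29 for the theca, stroma and luteal list, with 0 higher and 6 lower. The most abundant markers were Inha (12.42 in control, 12.02 in Uba3 cKO), Serpine2 (12.28 and 12.28) and Nr5a2 (12.04 and 12.16). None of the list is in another list, and how many of them oocytes express was not analysed here. These values bear only on the higher genes. Whether control pools held more cells of other ovarian types, which could account for lower markers, was not tested and stays open. An effect of Uba3 loss on the excess of higher genes also stays open and was not tested.

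The lower mitochondrial RNA did not depend on the choice among the authors' scaling and 4 rescalings. The highest median of the 22 kept mitochondrial RNAs over these rescalings was -0.24, as without rescaling, where -0.05 or more was needed. Its interval was -0.37 to -0.10 (2 SE over libraries, from the values before rescaling). Without rescaling the median was -0.38 under the stricter filter, which leaves out RNAs at low levels. The rescalings make totals, medians or distributions alike, and the sums of linear values were already within 1.05-fold. They moved the median little and cannot show a change in total RNA per oocyte. Scaling beyond that choice thus stays open. Weaker capture of RNA without a poly(A) tail could not be decided, with a median of -0.034 for the histone list (-0.46 to 0.40). That list includes H1f0, which is not replication-dependent. Of the mitochondrial RNAs called lower, mt-Nd6 (-0.88), mt-Rnr2 (-0.71), mt-Tq (-0.69) and mt-Rnr1 (-0.49) fell more than mt-Cytb (-0.38). The other kept transfer RNAs were not called. Among them mt-Tp, chosen after its value was seen, had a larger difference (-0.43, adjusted p = 0.0721) than mt-Cytb. The rest had -0.25 (mt-Tw) to -0.05 (mt-Ti) at control levels of 3.48 to 6.68, where differences may be shrunken. Mitochondrial RNAs were not compared by tail, so these values leave the capture explanation open. A general fall of respiratory chain transcripts also stays open, with -0.12 for 78 nuclear subunits (-0.27 to 0.03). An effect of Uba3 loss on mitochondrial transcription also stays open and was not tested.

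Genes that rose were enriched on the X chromosome, with an odds ratio of 2.16 (95% interval 1.64 to 2.82, adjusted Fisher's exact p = 1.97e-06 over 21 chromosomes). The odds ratio against autosomal genes was 2.07 (1.54 to 2.73) after the length and GC correction, above the bound of 1.5, which argues against that bias as the whole cause. It lay between 1.91 and 2.58 over the alternatives at the reported threshold. At an adjusted p under 0.01 it was 2.35 (95% interval 1.57 to 3.41). For log2 differences of 1 or more it was 6.18 (2.29 to 14.4), from only 7 X-linked and 31 autosomal genes. Genes that rose were also enriched on chromosomes 1 (1.39) and 13 (1.46) and depleted on 5, 9 and 11 (0.64 to 0.67), each with an adjusted p of 0.0304. The median log2 difference was 0.025 for X-linked and -0.007 for autosomal genes, and 0.002 and -0.013 after the length and GC correction. The correction thus took part of that gap away. An effect of Uba3 loss stays open and was not tested.

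Of the 40 kept genes nearest to Uba3 on its chromosome, 5% were called (0.611 to 16.9) against 8.14% of all tested genes. This argues against strain variants carried with the allele that change over 20% of these genes, the bound set. Variants that change fewer of them, or that lie elsewhere, would not be seen by this test. The sample titles name the other group only as control. If those mice carried the same Uba3 allele, both groups would share its variants and the test could not see them. Among mitochondrial RNAs with a control level of 5 or more, a minimum picked after the values were seen, the mean log2 difference was -0.56 for 4 light-strand and -0.33 for 11 heavy-strand genes (exact two-sided permutation p = 0.0586 over genes, which are not independent replicates). The minimum left out mt-Ty, named after its value was seen, at 4.97 in control (-0.23). The strand setting of the counting is unknown, so the counts may mix reads of both strands and this test cannot decide.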
